A study of Homo sapiens with 6 samples.

How the data were processed

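T-HESC cells, a telomerase-immortalised human endometrial stromal line, were infected with a lentivirus carrying PROK2 or with a control vector and then held for 48 h in starting medium, per the labels' protocols. Decidualization was induced for 72 h with 0.5 mM of the cAMP analog 8-Br-cAMP and 1 µM of the progestin MPA, per the labels' protocols. Total RNA of 6 samples was sequenced, 3 under the treatment label untreated and 3 under the label lentivirus infection. The labels do not say whether the 3 libraries of a label come from separate cultures. The p-values of single genes thus measure only the spread between these samples, which may be technical.

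The submitters' processing notes name bcl2fastq 2.17, cutadapt 1.18, HISAT2 and the genome build hg38. The quantification tool, the annotation release, the strand setting and any filter are not given in the sources used here. For each library the authors deposited a table of 60609 gene IDs with FPKM values (fragments scaled to gene length and to the library's mapped fragments), per the file headers. The same deposited tables hold TPM, which sums to the same total in every library, and a coverage value per gene, whose definition is not given in the sources used here. It was taken to be the mean read depth over the gene, not scaled to depth, which was not tested. A deposited series-wide table of FPKM held the same values within 0.1 percent in all 6 libraries for 60587 gene IDs and differed for 22. At most 21 rows of a library's table repeated a gene ID, and rows sharing an ID were summed. Counts of reads were not used here. Since the quantification of FPKM splits reads between overlapping genes and gene copies in a way not given in the sources used here, values of genes that share exons or near-identical copies are uncertain.

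The ratio of coverage to FPKM takes a modal value per library, held by 16.7% to 18.9% of genes with an FPKM above 1, which would give the aligned bases if coverage is the mean read depth. On that assumption they ranged from 6.51 to 8.48 Gb. The number of reads per gene is unknown. FPKM sums were 429267, 395410 and 439104 for the libraries labelled untreated and 461315, 466078 and 466628 for those labelled lentivirus infection. They are set in part by 5 abundant small RNA genes, RPPH1, RN7SL1, RN7SL2, RN7SK and RMRP. TPM divides by these sums and so lowers all genes in the second group.

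The contrast was lentivirus infection minus untreated, as labelled. Genes with a mean FPKM of at least 1 over the 6 libraries (13790, of which 11144 protein-coding) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Genes under the filter that were to be named in any case were tested singly by an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p under 0.1. Values are means ± SD over 3 libraries unless an SE is named, and pairs of values are given in the order untreated, lentivirus infection. Y-linked genes and XIST, 11 in all, are left out of the gene table. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used to join tables and draw plots. Gene types, transcript lengths and GC content came from GENCODE release 29 by gene ID, with 58502 IDs matched. Coordinates are those of the deposited tables, on hg38.

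There were 48 gene lists, drawn from general knowledge of decidualization, prokineticin signalling and stromal cell biology, and markers of epithelial, endothelial, leukocyte and pericyte cells. The 44 with at least 5 members past the filter were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. At the preset correlation camera takes genes as the replicates, so its small p-values do not measure the spread between libraries alone. With a correlation estimated per list, camera takes its degrees of freedom from the libraries. That version and fry were run beside it. Several lists share members, such as DKK1 and EGR1. The groups, the tests, the lists, the threshold, the alternatives (other than the 2 added) and the rule for the genes named were fixed before the data were examined. By that rule the text names PROK1, PROK2, PROKR1, PROKR2, PRL, IGFBP1 and FOXO1 whatever their values, and up to 12 genes in each direction that pass the threshold with groups that do not overlap. From each list with a member past the threshold it names up to 4 members, and from a list with none up to 2 of the highest mean FPKM. Members named because they passed adjusted over the list alone, and other genes so marked, were chosen after their values were seen.

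The model was tested on simulated data with the means and spreads of the 13790 genes, 3 libraries against 3, in 10 draws. The same 200 genes were changed in each draw. They were taken from genes above an FPKM of about 5, so recovery of lower genes was not tested. It recovered 30.1% of changes of 0.5 on the log2 scale, 80.7% of changes of 1 and 93.5% of changes of 2, with a mean of 6.8 false calls, and called 0 genes and 0 lists on average when nothing was changed. A list shift of -0.2 was called in 10 of 10 draws. Simulated genes were independent of each other, which real genes are not.

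Alternatives were pseudocounts of 0.1 and 0.01, no filter on low values and filters at a mean FPKM of 0.1 and 5, TPM, the series-wide table, quantile normalization, median centring, a robust variance prior, no variance trend, array weights, the replicate number as a block, symbols summed, and leaving out each library in turn. Coverage divided by the aligned bases so estimated for its library (depth-scaled coverage), and a per-library spline correction for GC content and transcript length (4 degrees of freedom each, 13706 genes or 99.4% with values), were added after seeing the data.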

Results

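Gene expression was measured by RNA sequencing in T-HESC, a line of human endometrial stromal cells immortalised with telomerase. The cells had been decidualized, that is, driven by a cAMP analog and a progestin towards the secretory state that stromal cells take on in the uterine lining before and during pregnancy. The series asked how overexpression of prokineticin 2, a secreted ligand of G protein-coupled receptors encoded by PROK2, alters decidualized cells, with a lentivirus to deliver the gene and a vector-infected control. The 6 libraries carry 2 treatment labels, untreated (n = 3) and lentivirus infection (n = 3). If the deposited coverage is the mean read depth over a gene, which the sources used here do not say, its most common ratio to FPKM puts the depth at 6.51, 6.67 and 7.77 Gb of aligned bases for the libraries labelled untreated. It would be 7.52, 8.48 and 7.59 Gb for those labelled lentivirus infection. Between 13590 and 14134 genes per library reached an FPKM of 1.

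PROK2 (ENSG00000163421.9, hg38 chromosome 3, 71771655 to 71785206, minus strand) was abundant in the libraries labelled untreated and close to 0 in those labelled lentivirus infection. Its FPKM was 650.7, 547.3 and 597.5 in the former and 0.143, 0.0532 and 0.127 in the latter. The means were 599 ± 51.7 (SD, n = 3) and 0.108 ± 0.0479 (SD, n = 3), a log2 fold change of -9.08 ± 0.089 (SE) with a limma adjusted p of 2.61e-08. In the libraries labelled untreated it ranked 33 of 11135 protein-coding genes by mean FPKM. The overexpressed gene thus lay on the side opposite to the treatment label in 6 of 6 libraries. The groups are therefore named by their labels only, as the libraries labelled untreated and the libraries labelled lentivirus infection, and every direction given is lentivirus infection minus untreated as labelled.

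The other prokineticin genes were at or near 0 in both groups. PROK1, the related ligand (chromosome 1), was at 0.149 ± 0.0934 FPKM in the libraries labelled untreated and 0.207 ± 0.130 in those labelled lentivirus infection (SD, n = 3 each; exact two-sided permutation p = 0.6). The receptor gene PROKR1 (chromosome 2) was listed at 0, 0 and 0.0361 FPKM against 0.0746, 0.0165 and 0 (exact permutation p = 0.7). The receptor gene PROKR2 (chromosome 20) was listed at 0 in all 6 libraries. Of these 4 genes only PROK2 entered the model. With 3 libraries against 3 the smallest exact permutation p is 0.1.

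Decidualization markers did not move as a group, and single members differed in both directions. IGFBP1 (chromosome 7), which encodes a secreted binding protein of insulin-like growth factors and is a classical marker of the decidual cell, was at 4.15 ± 0.664 FPKM in the libraries labelled untreated and 10.6 ± 4.16 in those labelled lentivirus infection (SD, n = 3 each). Its log2 fold change of 1.10 ± 0.29 (SE) did not pass over all genes (limma adjusted p = 0.151; exact permutation p = 0.1, the smallest possible). Without lentivirus infection replicate 1, whose IGFBP1 of 5.79 FPKM lay below those of the other 2 libraries, it did (limma adjusted p = 0.0499). Over all fits without 1 library the limma adjusted p ran up to 0.366, and the log2 fold change from 0.93 to 1.45. PRL (chromosome 6), which encodes decidual prolactin, was listed at 0, 0 and 0.0961 FPKM against 0.116, 0.0774 and 0 (exact permutation p = 0.7). FOXO1 (chromosome 13), a transcription factor of decidual gene expression, was at 67.0 ± 4.22 and 63.7 ± 6.48 FPKM (log2 fold change -0.07, limma adjusted p = 0.705; exact permutation p = 0.5). Without 1 library its log2 fold change ran from -0.16 to -0.03, and on TPM it was -0.22. Of the 39 markers tested, 24 lay above 0 and 15 below (camera adjusted p = 0.297). Adjusted over the list alone, IGFBP1 and FBLN1 were higher, and DKK1, ABI3BP and IL15 lower, against 0 over all genes tested. DKK1, an inhibitor of Wnt signalling, was at 697 ± 32.2 FPKM in the libraries labelled untreated and 528 ± 17.8 in those labelled lentivirus infection. DCN, the other of the 2 most abundant markers, was at 532 ± 163 and 398 ± 131 FPKM, a log2 fold change of -0.41 that ran from -0.70 to -0.24 without 1 library. That of ABI3BP was -0.32 on FPKM and -0.59 on depth-scaled coverage. A further 9 listed markers, PRL among them, fell under the expression filter.

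**Figure D1:**
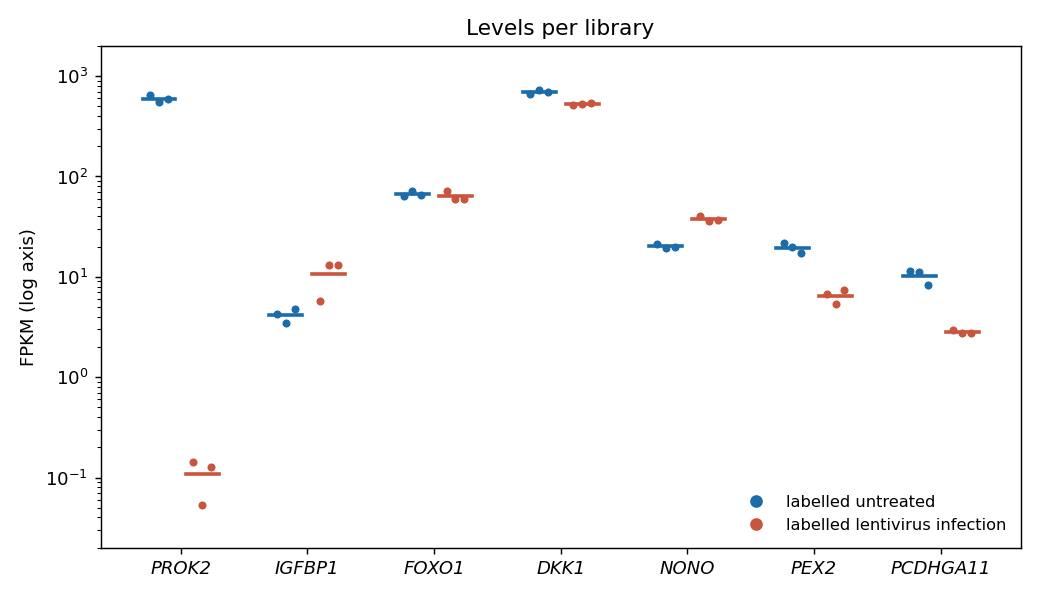
FPKM on a log axis for 7 genes in the 3 libraries labelled untreated and the 3 labelled lentivirus infection; points are libraries and lines are group means. PROK2 sits between 547 and 651 in the former and between 0.0532 and 0.143 in the latter, IGFBP1 and NONO lie higher and PEX2 and PCDHGA11 lower in the libraries labelled lentivirus infection, and FOXO1 overlaps.

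Across the transcriptome the first principal component separated the groups, while correlations overlapped and few single genes passed. On log2(FPKM + 1), Pearson correlations across genes were 0.974 to 0.979 for the 6 pairs of libraries within a group and 0.963 to 0.975 for the 9 pairs between groups, ranges that overlap. The first component held 33.5% of the variance, and the second held 19.5%. Genes are not independent replicates, so these correlations describe the libraries only. Of 13790 genes tested, 4 passed a limma adjusted p of 0.05, 1 higher and 3 lower in the libraries labelled lentivirus infection. At an unadjusted p under 0.05 there were 2507 genes, 1298 higher and 1209 lower, where 690 would be expected by chance. The 3 values of one group did not overlap the 3 of the other for 3569 genes (25.9%), where chance gives 10%.

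Besides PROK2, the genes that passed were NONO, PEX2 and PCDHGA11. NONO (ENSG00000147140.16, chromosome X, 71283192 to 71301168, plus strand), which encodes an RNA-binding protein of nuclear paraspeckles, rose from 20.2 ± 1.09 to 37.9 ± 2.56 FPKM (log2 fold change 0.88 ± 0.08 SE, limma adjusted p = 0.0469). PEX2 (ENSG00000164751.15, chromosome 8, 76980258 to 77001044, minus strand), which encodes a peroxisome assembly protein, fell from 19.5 ± 2.22 to 6.51 ± 1.04 FPKM (log2 fold change -1.45 ± 0.13 SE, limma adjusted p = 0.0469). PCDHGA11 (ENSG00000253873.6, chromosome 5, 141421047 to 141512975, plus strand), a protocadherin, fell from 10.2 ± 1.72 to 2.84 ± 0.0998 FPKM (log2 fold change -1.54 ± 0.13 SE, limma adjusted p = 0.0449). Its value is uncertain because genes of the gamma protocadherin cluster share their last exons. In each of the 3 genes all 3 libraries of one group lay apart from the other 3. None of the 3 calls was kept without untreated replicate 2 (adjusted p = 0.139 for each), and NONO and PEX2 also missed the threshold without any one of the other 5 libraries (adjusted p = 0.0678 to 0.154). PCDHGA11 passed only without untreated replicate 3 (adjusted p = 0.0127) and missed without untreated replicate 1 (0.0895) and lentivirus infection replicates 1 (0.0593), 2 (0.122) and 3 (0.0966). PROK2 passed in all 6 of these fits. The count of 4 fell to 1 without untreated replicate 2 and to 2 without lentivirus infection replicate 2, and rose to 12 without lentivirus infection replicate 1.

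**Figure D2:**
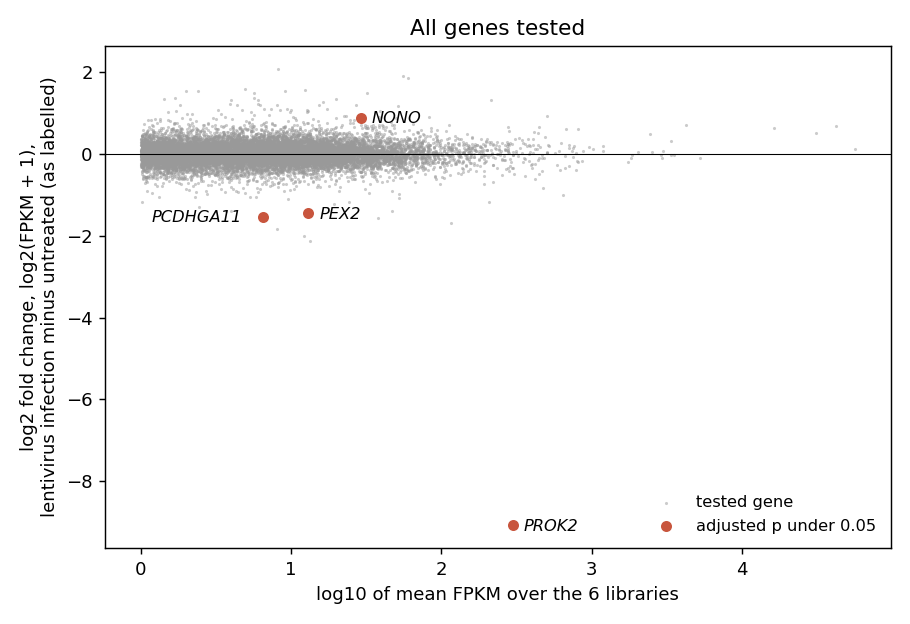
Log2 fold change on log2(FPKM + 1), lentivirus infection minus untreated as labelled, against the log10 of mean FPKM for the 13790 genes tested; each point is a gene. The 4 genes past a limma adjusted p of 0.05 are named, with PROK2 at -9.08, PCDHGA11 at -1.54, PEX2 at -1.45 and NONO at 0.88.

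Of 44 gene lists tested as groups, 9 passed an adjusted camera p of 0.05, 6 higher and 3 lower in the libraries labelled lentivirus infection. None of the 9 held with an estimated correlation between genes, where the lowest adjusted p was 0.250 and 6 lists had an unadjusted p under 0.05. For the matrix, NRF2, ERK and complement lists the estimate lay below the preset 0.01, so a higher correlation did not end those calls. That version of camera takes its degrees of freedom from the 6 libraries and not from the genes, which raises p. With fry, which tests whether a list's genes move on balance one way, 9 lists passed. The 6 shared with camera were the p53, NRF2, ERK, matrix, cAMP and complement lists, and the others were BMP signalling, antigen presentation and fatty acid synthesis. Beyond PROK2, no member of any list passed over all genes, so members are counted as adjusted over the list alone, and those named for that reason were chosen after their values were seen. On TPM the median of all genes was -0.12 on the log2 scale, against 0.007 on FPKM, and the lists are described relative to the other genes. Their TPM medians moved with it, to -0.36 for p53, -0.26 for NRF2 and -0.32 for ERK genes, and to 0.22 for mitochondrially encoded, 0.11 for cAMP, 0.08 for complement, 0.03 for cytosolic ribosomal and 0.01 for contractile genes.

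Target genes of p53 were lower in the libraries labelled lentivirus infection. Of 27 tested, 25 lay below 0 and 2 above, with a median log2 fold change of -0.22 (camera adjusted p = 2.97e-07; adjusted p = 0.250 with an estimated correlation; fry adjusted p = 0.00785). Adjusted over the list alone, 8 were lower and 0 higher. They were MDM2, which encodes the ubiquitin ligase of p53 (74.1 ± 2.70 to 50.7 ± 0.487 FPKM), the growth regulators CDKN1A (889 ± 40.6 to 673 ± 83.0) and BTG2 (8.61 ± 0.683 to 5.02 ± 0.0934), and TIGAR, RRM2B, ZMAT3, PHLDA3 and EDA2R. CCNG1, the most abundant member after CDKN1A, was at 101 ± 8.42 and 88.0 ± 7.65 FPKM. Its log2 fold change ran from -0.34 to -0.08 over the alternatives on all libraries, and from -0.27 to -0.14 without 1 library.

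Genes of the NRF2 and oxidative stress list were also lower. There were 17 of 30 below 0 and 13 above, with a median of -0.12 (camera adjusted p = 0.0115; adjusted p = 0.294 with an estimated correlation; fry adjusted p = 0.00785). The median was -0.07 with no filter on low values and -0.08 at a mean FPKM of at least 0.1. Adjusted over the list alone, 8 were lower and 1 higher. The lower ones included SRXN1, a sulfiredoxin (109 ± 3.46 to 72.9 ± 2.66 FPKM), SLC7A11, the cystine transporter (157 ± 11.4 to 111 ± 13.3), HMOX1, a heme oxygenase (23.4 ± 3.74 to 15.9 ± 1.42), and TXNRD1, a thioredoxin reductase (641 ± 17.1 to 532 ± 29.6), with OSGIN1, ME1, PRDX1 and GCLM. SOD3, the extracellular superoxide dismutase, was the higher one (3.66 ± 0.360 to 6.14 ± 0.487 FPKM), with a log2 fold change of 0.62 on FPKM and 0.18 on depth-scaled coverage. The most abundant members, FTL at 2506 ± 229 and 2561 ± 226 FPKM and TXN at 785 ± 7.02 and 793 ± 47.5, differed by less than their spread, and the sign of both turned on TPM.

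The list of ERK pathway feedback and immediate early genes was lower, with 18 of 27 members below 0 and a median of -0.18 (camera adjusted p = 0.0287; adjusted p = 0.294 with an estimated correlation; fry adjusted p = 0.0279). The median was -0.10 with no filter on low values and -0.13 at a mean FPKM of at least 0.1. Adjusted over the list alone, 7 were lower and 2 higher. EGR1, an immediate early transcription factor, was at 5.79 ± 0.502 FPKM in the libraries labelled untreated and 1.61 ± 0.450 in those labelled lentivirus infection (log2 fold change -1.39 ± 0.15 SE, limma adjusted p = 0.0520 over all genes). Over the fits without 1 library the limma adjusted p of EGR1 ran from 0.0491, without lentivirus infection replicate 1, to 0.168. CCND1, PHLDA1, EREG, DUSP6, SPRED1 and ETV5 were lower and DUSP5 and AREG higher. Of the 2 most abundant members, DUSP1 was at 408 ± 29.4 and 359.8 ± 23.7 FPKM and PHLDA1 at 219.7 ± 20.2 and 164 ± 15.2. The list missed the threshold on TPM (adjusted p = 0.0569), at a mean FPKM of at least 5 (0.0797), without untreated replicate 1 (0.108) and without lentivirus infection replicate 1 (0.0567).

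Genes of fibrillar collagens and the surrounding matrix were higher in the libraries labelled lentivirus infection, with 26 of 38 above 0 and a median of 0.11, which turned to -0.02 on TPM (camera adjusted p = 0.00445; adjusted p = 0.294 with an estimated correlation; fry adjusted p = 0.0292). The median was 0.20 without untreated replicate 1, 0.16 without untreated replicate 3, and 0.18 and 0.17 without lentivirus infection replicates 2 and 3. Adjusted over the list alone, 9 were higher and 0 lower. COL1A1, the main chain of type I collagen, was at 217 ± 31.4 FPKM in the libraries labelled untreated and 339.7 ± 27.7 in those labelled lentivirus infection. SPARC, a collagen-binding protein, was at 3029 ± 174 and 3752 ± 70.8 (log2 fold change 0.31 on FPKM and 0.16 on depth-scaled coverage), and the proteoglycan gene BGN at 2.62 ± 0.202 and 5.51 ± 0.565. The others were COL5A1, COL12A1, EFEMP1, FBLN1, FBLN2 and MFAP2. FN1, which encodes fibronectin, was at 2019 ± 98.6 and 2075 ± 194 FPKM, a log2 fold change of 0.04 that turned to -0.11 on TPM and -0.03 under quantile normalization. Of 16 basement membrane genes, 11 lay above 0 (camera adjusted p = 0.0745, not past the threshold). COL4A1 (68.6 ± 1.25 to 102 ± 8.14 FPKM), COL4A2 and NID1 were higher and LAMC2 lower, adjusted over the list alone.

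Contractile and SRF target genes had 19 of 28 members above 0 and a median of 0.14 (camera adjusted p = 0.0498; adjusted p = 0.447 with an estimated correlation; fry adjusted p = 0.0707). CNN2 (34.1 ± 2.03 to 45.8 ± 0.720 FPKM) and MYL9 (33.7 ± 1.08 to 42.7 ± 2.19) were higher adjusted over the list alone, and the most abundant members, ACTB at 783 ± 48.6 and 635 ± 55.2 FPKM and CALD1 at 345 ± 84.7 and 541 ± 134, lay on either side of 0. This call was lost on TPM (adjusted p = 0.0569), under the GC and length correction (0.268, with a median of 0.08), and without untreated replicate 1 (0.128), untreated replicate 3 (0.0747) or lentivirus infection replicate 3 (0.0715). Complement genes had 13 of 16 members above 0 and a median of 0.18 (camera adjusted p = 0.0287; adjusted p = 0.294 with an estimated correlation; fry adjusted p = 0.0292). C2 (1.70 ± 0.339 to 2.96 ± 0.267 FPKM) and SERPING1 (1.46 ± 0.226 to 2.97 ± 0.741), the C1 inhibitor, were higher adjusted over the list alone, while the abundant CD59 and C1R were at 180.3 ± 36.9 and 149 ± 31.1, and at 101 ± 13.2 and 121 ± 12.2. The log2 fold change of CD59, -0.28, ran from -0.46 to -0.12 without 1 library. On depth-scaled coverage the log2 fold change of C2 was 0.05 against 0.56 on FPKM, that of SERPING1 0.46 against 0.68, and the complement median 0.08 (camera adjusted p = 0.0209). The complement call was lost at a mean FPKM of at least 5 (adjusted p = 0.405, with a median of 0.08), under the GC and length correction (0.0514, with a median of 0.10), and without untreated replicate 2 (0.0531), untreated replicate 3 (0.0799) or lentivirus infection replicate 1 (0.0770).

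The cAMP and CREB target genes, which answer to the cAMP arm of the decidualization stimulus, had 18 of 22 members above 0 and a median of 0.23 (camera adjusted p = 0.0160; adjusted p = 0.294 with an estimated correlation; fry adjusted p = 0.0444). No member passed adjusted over the list alone with limma, while 7 were higher and 1 lower at an unadjusted p under 0.05. PRKAR2B, a regulatory subunit of protein kinase A, was at 0.986 ± 0.205 and 2.36 ± 0.669 FPKM and the nuclear receptor NR4A3 at 2.92 ± 0.440 and 4.09 ± 0.214, both chosen after their values were seen. On depth-scaled coverage the log2 fold change of PRKAR2B was 0.17 against 0.74 on FPKM, and the list's median 0.13 (camera adjusted p = 0.0115). The 2 most abundant members, the phosphodiesterases PDE4D (53.6 ± 7.03 and 48.7 ± 7.58 FPKM) and PDE4B (41.6 ± 3.66 and 32.7 ± 3.50), lay below 0, with log2 fold changes of -0.14 and -0.34 on FPKM and -0.04 and -0.09 on depth-scaled coverage. That of PDE4D ran from -0.26 to -0.03 without 1 library. The call was lost at a mean FPKM of at least 5 (adjusted p = 0.131) and without lentivirus infection replicate 1 (0.0770). The genes that answer to the progestin arm, the MPA and glucocorticoid receptor targets, did not pass (24 tested, 16 above 0, camera adjusted p = 0.0788). Adjusted over the list alone, CEBPD (227 ± 12.4 to 337 ± 34.9 FPKM), CRISPLD2, MFSD2A, ANGPTL4, MT1E and MT1X were higher and ERRFI1 lower. The log2 fold change of MFSD2A was 1.20 on FPKM and 0.67 on depth-scaled coverage.

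Cytosolic ribosomal protein genes had 63 of 73 members above 0 and a median of 0.17 (camera adjusted p = 4.29e-06; adjusted p = 0.349 with an estimated correlation, which was 0.0917 against the preset 0.01; fry adjusted p = 0.0531). The log2 fold changes of single members ran from -1.68 to 0.90. RPL28 (36.5 ± 4.34 to 60.2 ± 6.03 FPKM) and RPL14 (32.8 ± 3.60 to 46.5 ± 3.12) were higher and RPS13 (353 ± 7.94 to 253 ± 21.4) lower adjusted over the list alone. On depth-scaled coverage the log2 fold change of RPL28 was 0.38 against 0.71 on FPKM, and that of RPL14 0.30 against 0.49. The most abundant, RPL13A and RPLP0, were at 905 ± 76.2 and 1009 ± 32.6 FPKM and at 848 ± 223 and 738 ± 149. Of 13 listed mitochondrially encoded protein genes, MT-ATP6 fell under the expression filter. The 12 tested all lay above 0, with a median of 0.34 (camera adjusted p = 0.00165; adjusted p = 0.485 with an estimated correlation, which was 0.594; fry adjusted p = 0.137). MT-ND1 (3.36 ± 0.819 to 5.79 ± 0.551 FPKM) was higher adjusted over the list alone, MT-CO1 was at 724 ± 93.2 and 749.5 ± 23.8, with a sign that turned on TPM, and MT-CO3 at 139 ± 33.1 and 179 ± 20. The list means of single libraries overlapped between the groups. So did the share of mitochondrially encoded genes in protein-coding FPKM, with no clear rise in total. It was 0.404%, 0.326% and 0.309% in the libraries labelled untreated and 0.394%, 0.357% and 0.374% in those labelled lentivirus infection. The list's median log2 fold change was 0.21 without untreated replicate 2. The call was lost at a mean FPKM of at least 5 (camera adjusted p = 0.0826), which only 6 of these genes reached.

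**Figure D3:**
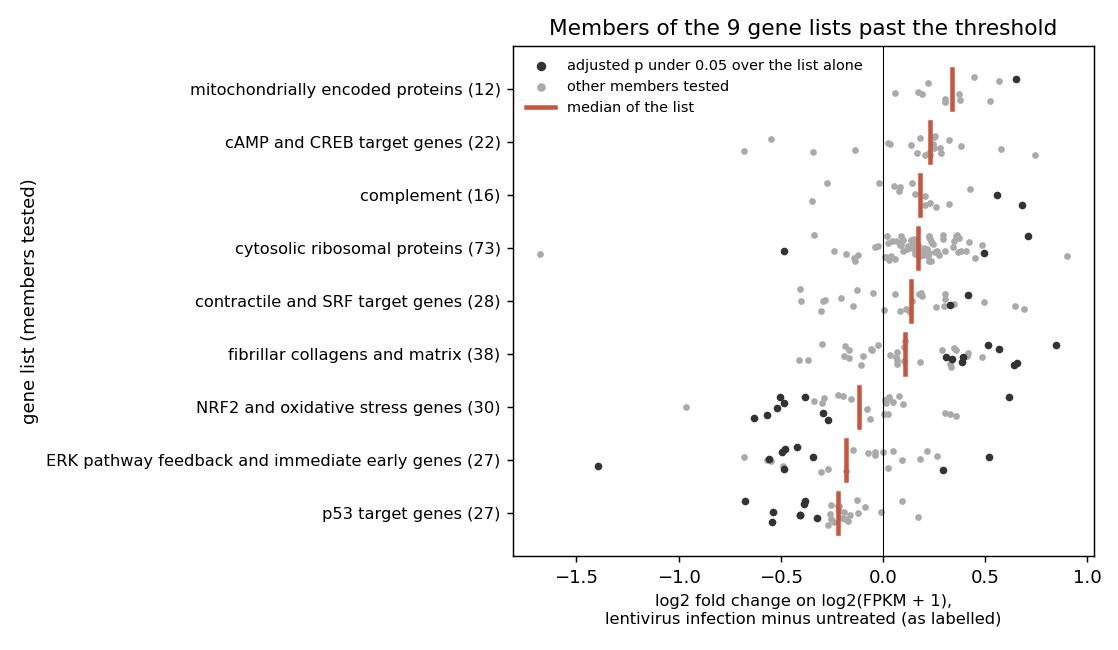
Log2 fold changes on log2(FPKM + 1), lentivirus infection minus untreated as labelled, of the members of the 9 lists past the camera threshold; each point is a gene, black where its adjusted p over the list alone is under 0.05, and the red bar is the list's median. The medians run from -0.22 for p53 target genes to 0.34 for mitochondrially encoded proteins, and that of fibrillar collagens and matrix, 0.11 here, is -0.02 on TPM.

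**Figure D4:**
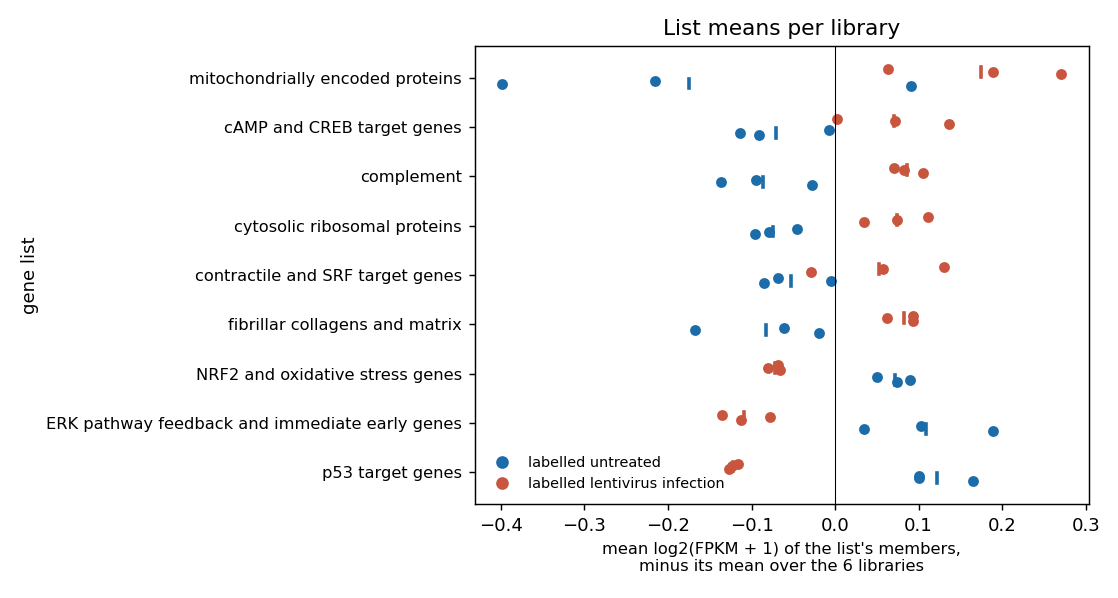
Mean log2(FPKM + 1) of each list's members in each library, minus the list's mean over the 6 libraries; points are libraries, 3 per label, and ticks are group means. The p53, NRF2 and ERK lists lie lower in all 3 libraries labelled lentivirus infection than in any labelled untreated, the mitochondrially encoded and contractile lists overlap, and on TPM the median change of fibrillar collagens and matrix turns from 0.11 to -0.02.

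Genes reported as targets of prokineticin 1 in endometrium and decidua did not pass as a list (12 tested, 5 above 0 and 7 below, camera adjusted p = 0.264). EGR1 and DKK1, given among the ERK and decidualization genes, were lower adjusted over the list alone, and CCN2, a matricellular growth factor, was at 328 ± 34.2 and 425 ± 46.6 FPKM. Endometrial receptivity genes (camera adjusted p = 0.655, with a median of -0.06 and a mean of 0.004) and Wnt signalling genes (0.533) had DKK1 as their 1 member lower adjusted over the list alone. Prostaglandin genes did not pass (0.348), with a median of -0.04 and a mean of 0.09, which differ in sign. Steroid hormone genes did not pass (0.0745), with CYP1B1 and NR3C1 lower adjusted over the list alone. The G protein and calcium signalling list, through which prokineticin receptors act, did not pass either (0.886).

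Few markers of epithelial, endothelial and leukocyte cells passed the expression filter. These lists had 4, 3 and 3 members past it, too few to test as lists, and none of these genes passed over all genes or adjusted over the list alone with limma (0 at an unadjusted p under 0.05). KRT8 was at 7.86 ± 1.02 and 10.3 ± 1.79 FPKM and KRT19 at 3.55 ± 0.343 and 4.17 ± 1.27 among the epithelial markers. EGFL7 was at 13.1 ± 1.04 and 11.9 ± 1.24 and TEK at 4.61 ± 0.395 and 5.28 ± 0.527 among the endothelial ones. CD68 was at 13.7 ± 1.96 and 14.9 ± 3.86 and CD163 at 1.02 ± 0.317 and 1.32 ± 0.453 among the leukocyte ones. Pericyte and smooth muscle markers (camera adjusted p = 0.535; CNN1 and MCAM higher adjusted over the list alone, MCAM with a log2 fold change of 0.43 on FPKM and 0.20 on depth-scaled coverage) and stromal fibroblast markers (0.886; COL1A1 higher, MME and NT5E lower) did not pass.

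The lists of cell growth, stress, metabolism and signalling named next did not pass. Adjusted camera p was 0.224 for S phase and DNA replication (21 of 40 listed genes tested) and 0.115 for G2 and mitosis (15 of 46). The rest of both lists, MKI67 and CDK1 among them, fell under the expression filter. Adjusted camera p was 0.418 for apoptosis regulators, 0.312 for heat shock proteins and 0.655 for hypoxia and glycolysis. It was 0.829 for lysosome and autophagy, 0.221 for nuclear-encoded oxidative phosphorylation, 0.190 for cholesterol synthesis and 0.348 for Notch signalling. These 9 lists, with the prostaglandin and G protein lists, were the 11 that had 0 members past the limma threshold adjusted over the list alone. At an unadjusted p under 0.05 the 11 lists held 33 higher and 13 lower members, in total a share near that over all genes (2507 of 13790). The members leaned to the higher side more than all genes did (1298 higher and 1209 lower), which was not tested. For senescence the adjusted camera p was 0.886. Its members IGFBP4 (2052 ± 152 to 2868 ± 168 FPKM) and the cell cycle inhibitor CDKN1C (6.0 ± 0.921 to 13.6 ± 4.43) were higher and CDKN1A lower adjusted over the list alone. For the IGF axis it was 0.131, with IGFBP4 higher adjusted over the list alone.

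A further set of lists did not pass with camera but held members past the threshold adjusted over the list alone. Replication-dependent histone genes came nearest (21 tested, 14 above 0, camera adjusted p = 0.0507), with 7 higher, among them HIST1H1D (48.8 ± 2.94 to 73.7 ± 5.44 FPKM), and 2 lower, HIST1H2AC and HIST2H2BE. Adjusted camera p was 0.0781 for antigen presentation (HLA-B higher; fry adjusted p = 0.0279), 0.109 for fatty acid synthesis (SCD higher; fry adjusted p = 0.0356), 0.131 for TGF-beta and activin signalling (TGFBR2 lower, BAMBI higher) and 0.131 for integrins and cell adhesion (6 higher, with ICAM1 and CD44 among them, and NECTIN3 lower). It was 0.132 for nuclear long noncoding RNAs (SNHG8 lower, with a log2 fold change of -0.44 on FPKM and -0.11 on depth-scaled coverage), 0.735 for YAP and TEAD targets (NT5E lower), 0.864 for NF-kB and cytokine genes (ICAM1 higher) and 0.767 for matrix-degrading enzymes (ADAMTS5 lower, PLAT and ADAMTS4 higher).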

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

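Coverage and the GC and length correction were alternatives chosen after the data were seen; the others were not. PROK2 kept its direction and its call in every alternative, between -12.41 and -9.02 on the log2 scale (adjusted p 6.19e-09 to 2.51e-05), and between -9.14 and -9.02 without 1 library. The counts of other genes moved with the setting. Genes past the threshold were 4 (1 higher, 3 lower) as reported, of which 3 were changed at least 2-fold. They were 2 (0 higher) with a pseudocount of 0.1 and 2 (0 higher) with 0.01. They were 1 (0 higher, 1 lower), PROK2, with no filter on low values, with quantile normalization, with no variance trend and with the replicate block. For these 4 settings the genes changed at least 2-fold were 1, 1, 1 and 1. A mean FPKM of at least 5 gave 15 genes (4 higher, 11 lower), TPM 26 (3 higher, 23 lower, 12 at least 2-fold), the robust variance prior 8 (2 higher, 6 lower, 5 at least 2-fold) and array weights 68 (31 higher, 37 lower, 9 at least 2-fold). Coverage gave 12 (7 higher, 5 lower, 5 at least 2-fold), median centring 6 (2 higher, 4 lower) and the GC and length correction 5 (2 higher, 3 lower). All 4 reported genes were shared with the calls on TPM, with array weights, with the robust prior, and at a mean FPKM of at least 5, and 2 with those on coverage. Without 1 library the counts ran from 1 to 12 in all, 0 to 5 higher, 1 to 7 lower and 1 to 12 at least 2-fold. Fewer genes tested at a mean FPKM of at least 5 and more without a filter change the adjustment; TPM lowers all genes of one group by construction. For the other settings the cause was not tested.

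Lists past the threshold were 9 as reported, 16 of 47 with no filter on low values, 0 with an estimated correlation, and 7 to 13 without 1 library. With an estimated correlation the adjusted p was 0.250 for p53 target genes, 0.294 for fibrillar collagens and matrix, NRF2, cAMP, ERK and complement genes, 0.349 for cytosolic ribosomal, 0.447 for contractile and 0.485 for mitochondrially encoded proteins. With fry it was 0.0531 for cytosolic ribosomal, 0.137 for mitochondrially encoded and 0.0707 for contractile genes. A mean FPKM of at least 5 gave 0.131 for cAMP, 0.405 for complement, 0.0797 for ERK and 0.0826 for mitochondrially encoded genes. TPM gave 0.0569 for contractile and 0.0569 for ERK genes. Contractile genes had 0.0687 with no variance trend, 0.0514 with array weights, 0.0617 with the replicate block, 0.0501 with symbols summed and 0.268 with the GC and length correction. Complement genes had 0.0631 with the replicate block and 0.0514 with the GC and length correction. Without 1 library the adjusted p ran from 0.00717 to 0.0770 for cAMP, 0.0161 to 0.0799 for complement, 0.0154 to 0.128 for contractile and 0.0168 to 0.108 for ERK genes. The calls of p53, matrix and NRF2 genes were lost only with an estimated correlation, among the alternatives tried. The robust prior has no counterpart in camera and was not run for lists.

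The same replicate numbers do not pair the libraries. Deviations from the group means correlated at -0.03, -0.12 and 0.02 for numbers 1, 2 and 3, no library correlated best with its own number, and the replicate block left 1 gene and 7 lists past the threshold. Of 149 named genes, PROK2 left out, only NONO, PEX2 and PCDHGA11 passed as reported. Most values kept were therefore of genes that did not pass in either fit. Over the settings on all libraries 2231 values kept direction and side of the threshold, 20 no longer passed, 53 newly passed and 6 moved. All values that no longer passed were of NONO, PEX2 and PCDHGA11. Without 1 library the numbers were 865, 17, 3 and 0, and the only call kept was that of PCDHGA11 without untreated replicate 3. Signs turned for genes with small differences: FN1 was -0.11 on TPM and -0.027 with quantile normalization (-0.0066 to 0.12 without 1 library), FTL -0.11 on TPM, -0.16 with quantile normalization and -0.054 with the GC and length correction (-0.029 to 0.11), and TXN -0.13 on TPM and -0.0052 with median centring (-0.028 to 0.058). CD68 was -0.040 on TPM (-0.10 to 0.20 without 1 library) and MT-CO1 -0.085 (-0.025 to 0.16). KRT19 ran from -0.034 to 0.27 and RPLP0 from -0.39 to 0.0028 without 1 library. Sizes, not signs, moved by over 1.5 times without 1 library for FOXO1 (-0.16 to -0.03), DCN (-0.70 to -0.24), CD59 (-0.46 to -0.12), PDE4D (-0.26 to -0.03), EGFL7 (-0.19 to -0.05) and CD163 (0.04 to 0.28). On depth-scaled coverage some named genes changed less than on FPKM. The log2 fold changes on FPKM and on coverage were 0.71 and 0.38 for RPL28, 0.49 and 0.30 for RPL14, 0.31 and 0.16 for SPARC, 0.43 and 0.20 for MCAM, -0.57 and -0.24 for GBP1, 1.20 and 0.67 for MFSD2A, -0.44 and -0.11 for SNHG8, 0.45 and 0.19 for PHGDH, 0.34 and 0.08 for KRT8, 0.19 and 0.05 for CD163, -0.30 and -0.20 for ACTB, -0.28 and -0.18 for CD59 and -0.41 and -0.27 for DCN. They were larger on coverage for ABI3BP (-0.32 and -0.59), PRPS2 (0.68 and 1.10) and FN1 (0.04 and 0.06). Depth is estimated only as aligned bases, so differences of genes near 0, PRL and the receptors among them, cannot be shown at the depth behind each value.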

Other observations

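Tests of the PROK2 labels and of the isoforms of NONO, PEX2 and PCDHGA11 were chosen only after the result was seen, and those of other splits were not. Predictions for p53 targets were written before their tests, though these genes were picked as 1 of 44 lists once their call was known. Coverage and the GC and length correction, the latter used for p53 targets, were measures added after the data were seen. In the libraries labelled untreated and those labelled lentivirus infection, BMP6, a bone morphogenetic protein, was at 5.08 ± 0.192 and 11.7 ± 1.52 FPKM, and the BMP antagonists GREM1 and NOG were at 360.1 ± 22.2 and 516 ± 54.7, and at 13.6 ± 2.14 and 20.4 ± 1.72 (SD, n = 3 each). These 3 were higher adjusted over the list alone among 21 BMP signalling genes, of which 15 lay above 0 (camera adjusted p = 0.177; fry adjusted p = 0.00785). Among 33 angiogenic factors and receptors (camera adjusted p = 0.880), the semaphorins SEMA3C (82.9 ± 4.37 to 51.2 ± 1.93 FPKM) and SEMA3A (134 ± 10.5 to 93.2 ± 11.3) were lower, and the chemokine CXCL12 (74.2 ± 5.78 to 112 ± 3.95), NRP2 and ANGPTL4 were higher adjusted over the list alone. The log2 fold change of NRP2 was 0.47 on FPKM and 0.25 on depth-scaled coverage. All of these genes were chosen after their values were seen, and none passed over all genes (limma adjusted p 0.0520 for BMP6 and SEMA3C).

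Interferon-stimulated genes did not move as a list (39 tested, 22 below 0, camera adjusted p = 0.176), but 7 were lower and 0 higher adjusted over the list alone. They were SAMD9L (9.48 ± 0.405 to 5.06 ± 0.598 FPKM), STAT1 (87.4 ± 4.46 to 68.2 ± 4.34), TRIM22, IFIT5, SAMD9, DDX58 and GBP1 (log2 fold change -0.57 on FPKM and -0.24 on depth-scaled coverage). In the list of the unfolded protein and integrated stress responses (36 tested, camera adjusted p = 0.798, with a median of 0.07 and a mean of -0.01), TRIB3 (10.6 ± 0.480 to 5.71 ± 0.938 FPKM), ASNS, the asparagine synthetase (14.1 ± 1.184 to 8.39 ± 1.47), PPP1R15A and SLC7A11 were lower and PHGDH (log2 fold change 0.45 on FPKM and 0.19 on depth-scaled coverage) higher adjusted over the list alone. No gene of either list passed over all genes. The small RNA genes RPPH1, RN7SL1, RN7SL2, RN7SK and RMRP together took 32.7%, 26.7% and 32.3% of the FPKM sum in the libraries labelled untreated. In those labelled lentivirus infection they took 37.2%, 36.5% and 36.9%. Other small RNA genes are not in these shares. RN7SL1, the RNA of the signal recognition particle, was at 33059 ± 8459 and 51764 ± 1849 FPKM (log2 fold change 0.68, limma adjusted p = 0.175). Of 7 gene classes tested with camera, such as antisense and long intergenic RNAs, 0 passed (lowest adjusted p 0.137; adjusted p = 0.914 with an estimated correlation; 2 at an unadjusted p under 0.05). On coverage in place of FPKM, 12 genes passed, among them PRPS2 at 1.10 (0.68 on FPKM, limma adjusted p = 0.0673), RNMT at 1.06 (0.75 on FPKM, 0.0675), BMP6 at 1.06, MDM2 at -0.65 and SRXN1 at -0.57 on the log2 scale (limma adjusted p 0.0180 to 0.0429).

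PROK2 lay opposite to the label in 6 of 6 libraries, in 2 whole groups of 3, which argues against 1 library under a wrong label. The series-wide columns held the FPKM of the library table of the same code for 60587 of 60609 gene IDs, which argues against tables exchanged between these 2 places and leaves open an error made before both. In 5 libraries that code is also in the sample's title, while the title of the remaining one, of the group labelled untreated, holds another code. A candidate explanation that the 6 of 6 libraries leave standing is that the treatment labels were exchanged between the groups, or that lentivirus infection names the cells with the control vector. If so, each direction given would be the reverse of the effect of PROK2, and a difference between vectors or cultures was not tested.

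Target genes of p53 were lower in the libraries labelled lentivirus infection, with a median of -0.22 on the log2 scale. The median stayed at -0.24 after correction for GC content and length, which argues against these as its whole cause. It was -0.22 after quantile normalization, which brings the small RNAs to a like share. That test could hardly have ended otherwise, since scaling shifts genes in common and the median of all genes was already 0.007. The all-gene median itself argues against scaling as the whole cause. Leaving out 1 library gave adjusted p values of 2.56e-05 at most, against 1 library deciding the call. With a correlation estimated at 0.0174, near the preset 0.01, the call was lost (adjusted p = 0.250). The matrix (0.0051), NRF2 (-0.015), ERK (-0.0072) and complement (-0.015) lists lost theirs too, at estimates below the preset. A higher correlation thus cannot be the cause for those lists. Camera with an estimated correlation also takes its degrees of freedom from the 6 libraries and not from the genes, which raises p. For p53 genes the unadjusted camera p went from 6.75e-09 at the preset to 0.00568. Their estimate was only slightly above the preset, and the change of correlation and that of degrees of freedom were not run apart. A difference between the groups in PROK2, vector or culture stays open, untested, since the design cannot part these.

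NONO, PEX2 and PCDHGA11 passed on FPKM, whose value depends on how reads are apportioned between the isoforms of a gene. On depth-scaled coverage the log2 change was 0.71 ± 0.19 (SE) for NONO against 0.88 ± 0.08 on FPKM, -1.17 ± 0.18 for PEX2 against -1.45 ± 0.13, and -1.49 ± 0.12 for PCDHGA11 against -1.54 ± 0.13. How coverage was computed is not given in the sources used here, and it may rest on the same assignment of reads, so isoform apportioning stays open for all 3 genes. The calls of NONO (limma adjusted p = 0.151) and PEX2 (0.0708) ended there because the change was smaller and its SE larger, and that of PCDHGA11 stood (0.0393). Reads shared within the protocadherin cluster may also set the value of PCDHGA11, and no biological explanation was tested.

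With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 4 genes past the threshold and the highest other split 5, and 2 of the 10 gave at least 4. At an unadjusted p under 0.05 the real split gave 2507 genes and the highest other 919, and 1 of the 10 gave as many. For gene lists the real split gave 9 and the highest other 5, and again 1 of the 10 gave as many.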
